A study of Caenorhabditis elegans with 16 samples.

How the data were processed

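RNA was measured by sequencing in 16 libraries of germline tumor dissected from Caenorhabditis elegans adults, with 4 libraries each for control animals (0 h of auxin) and for animals given 1 mM auxin for 2 h, 4 h or 48 h. Per the labels' protocols, synchronised larvae were grown for 48 h at 25 °C, total RNA was extracted, and ribosomal RNA was depleted before library preparation. The series describes its libraries as 4 biological replicates per group; the labels do not say how each was collected.

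The deposited values are a signal per gene, named CPM (reads scaled to a fixed total per library) by the authors, in 2 tables. One table holds 10 libraries (control 1 to 4, 2 h 1 and 2, and 48 h 1 to 4) and the other holds 6 (2 h 3 and 4, and 4 h 1 to 4). STAR 2.0.4b, Subread, featureCounts 1.4.5, edgeR and limma are named in the submitters' processing notes, without their settings. The genome build, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. As deposited, the columns sum to between 1020920 and 1035945 because some genes are listed on repeated lines. With 1 line kept per gene, 46536 genes remain and each column holds between 99.8% and 99.9% of the total that CPM is scaled to.

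Every nonzero value was a whole multiple of the value of 1 read in its library (100% of values, tolerance 0.1 read), so whole reads could be recovered. The recovered library totals were 17760706 to 33888940 reads, of which 8929146 to 20599885 fell in protein-coding genes. A count of 0 allows a level of up to 3 reads, which is 0.0885 to 0.169 CPM depending on the library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom was 3.62, so all 16 were kept as separate libraries. P-values measure the spread between these libraries.

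Each comparison was tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend) on log2(CPM + 1), 2-sided, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Genes were tested where at least 2 libraries of the table reached 1 CPM. Because the values were deposited as 2 tables, comparisons were made within a table; whether the tables are separate batches is not given in the sources used here. The 2 h, 48 h and control libraries of the first table shared 1 fit, and the 2 h and 4 h libraries of the second shared another. The 4 h libraries and the controls never share a table, so that comparison was a joint fit of the 16 libraries with a term for the table, linked through the 2 h libraries. Its level differences across tables are printed as levels only.

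Gene groups came from 25 lists: Notch pathway, known Notch targets, germline stem cell regulators, meiotic prophase, DNA replication, mitotic cell cycle, spermatogenesis, major sperm proteins, oogenesis and maternal genes, germ granule and small RNA, sex determination, apoptosis and engulfment, germline chromatin, ribosomal proteins, histone genes, mitochondrially encoded genes, markers of intestine, muscle, neurons, cuticle and epidermis and somatic gonad, heat shock and unfolded protein, xenobiotic and oxidative response, immune and infection response, and X-linked genes. Lists with at least 5 tested members were tested with camera (limma), with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 113 tests of lists and comparisons. Gene names came from the deposited tables; coordinates and lengths came from the Ensembl annotation of WBcel235, in which 46363 of the 46536 gene IDs were found. That build was not stated to be the authors' build.

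The named genes are 6 genes given in every comparison (lst-1, sygl-1, lag-1, glp-1, gld-1 and gld-2). To these were added the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean reached 5 CPM in the higher group. From each list, the 2 called members with the largest rise and the 2 with the largest fall were added, or the member with the smallest p where none was called; the text names a selection of these list members and gives the rest as counts. List members named for calls after centring alone were chosen after their values were seen. The results of 1 gene are not reported here, for a reason set from outside that does not concern its values, and it was left out of the search for far libraries after its result had been seen. The groups, tests, lists, naming rule and the first set of other settings were fixed before the data were examined.

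That set held pseudocounts of 0.5 and 0.1, no filter and a stricter filter of 5 CPM, centring each library on its median log ratio over genes of at least 10 CPM, a replicate block, limma without the trend, only the groups compared, a joint fit, leaving out each library in turn, and edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads. Removal of a length trend from each library (loess, span 0.5), leaving out 3 libraries that stood apart, and leaving out each 2 h library from the 4 h comparison were added after seeing the data. The gene tests were tested on simulated data with 200 changed genes. For 48 h against control, 7484 simulated genes were tested and limma recovered 100% of the genes changed by 1 log2 unit; for 4 h against control, with 7342 genes tested, it recovered 67%. The simulation held no differences between libraries of a group other than sampling and gene-wise noise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.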

Results

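The 16 libraries came from dissected germline tumors of 1-day-old adults that carried the alleles ar202 of glp-1, q485 of gld-1 and q497 of gld-2, an altered lag-1 gene and a transgene expressing TIR1 from the gld-1 promoter. LAG-1 is the DNA-binding transcription factor of the Notch pathway, GLP-1 is the germline Notch receptor, and GLD-1 and GLD-2 promote meiotic entry. TIR1 is a plant auxin receptor that, with auxin, directs the breakdown of proteins carrying a matching degron. The series is a time course of auxin treatment, so the comparisons ask which transcripts differ after 2 h, 4 h and 48 h. The stated growth was 48 h in every group, as long as the longest auxin time. The 48 h animals may thus have had auxin through that growth, and the 2 h and 4 h animals for a part of it. Length of exposure and stage at exposure cannot be told apart at 48 h. No group had auxin without the altered lag-1 gene, so effects of auxin itself are not separated. The labels do not describe the change in lag-1; that it adds a degron is inferred from the auxin design. No measurement of LAG-1 protein was analysed here, and lag-1 RNA would not check its loss.

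Each group had 4 libraries, with recovered totals of 17760706 to 33888940 reads. Of the 10 libraries that share a table, 3 stood apart in their RNA composition. Ribosomal RNA took 53.3% of control library 1, 51.7% of control library 3 and 44.9% of 48 h library 1, against 32.2% to 36.2% in the other 7. After median centring, the longest length quintile of protein-coding genes lay below the shortest by -0.78, -0.64 and -0.48 (log2) in these 3 libraries, against -0.02 to 0.40 in the other 7. In the 6-library table the ribosomal share was 37.7% to 44.6%.

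**Figure D1:**
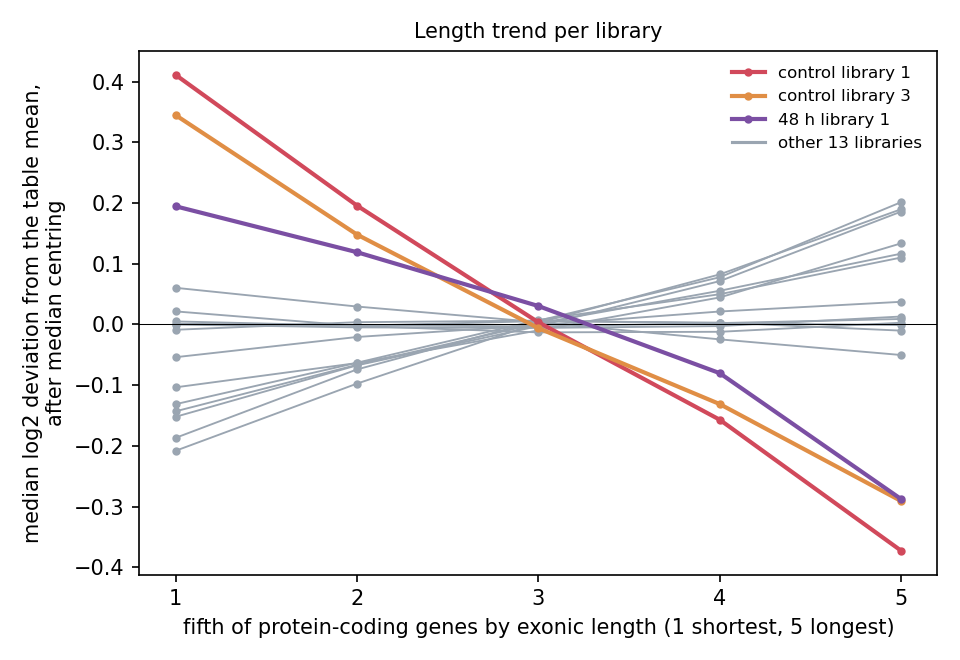
Median log2 deviation of protein-coding genes from the table mean (vertical axis, log2 units, after median centring) by quintile of exonic length (horizontal axis, 1 shortest to 5 longest), 1 line per library. Control libraries 1 and 3 and 48 h library 1 slope downward, from 0.41, 0.34 and 0.19 in the shortest quintile to -0.37, -0.29 and -0.29 in the longest.

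After 2 h of auxin, the 2 best-known germline Notch targets were lower. The lst-1 transcript (WBGene00003083, chromosome I, 10588501 to 10590465 in WBcel235), which encodes a stem cell regulator, was 18.1 ± 0.993 CPM (SD, n = 2) against 55.1 ± 24.9 CPM (SD, n = 4) in controls. The sygl-1 transcript (WBGene00012104, chromosome I, 12483809 to 12486235), its partner in stem cell maintenance, was 2.01 ± 0.920 CPM (SD, n = 2) against 15.3 ± 9.89 CPM (SD, n = 4). The log2 fold changes were -1.46 ± 0.31 (SE) and -2.30 ± 0.45 (SE), and 2 h libraries 1 and 2 lay below every control. Of all genes tested in this comparison, 18.8% had groups that did not overlap, in either direction. Over all genes, limma gave adjusted p = 0.520 for lst-1 and 0.404 for sygl-1, so neither passed; adjusted over the list alone, 2 of the 8 tested known Notch targets fell and 0 rose, and these were both.

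The 2 h comparison called 0 of 7684 genes with limma, with 429 genes at an unadjusted p under 0.05. edgeR on the recovered reads called 0 and DESeq2 called 29. Without control libraries 1 and 3 limma called 0 (adjusted p = 0.103 for lst-1 and 0.423 for sygl-1). Leaving out 48 h library 1 as well, which is not in this comparison but enters the variance of the shared fit, gave 26 (21 up, 5 down) with the same folds, lst-1 and sygl-1 among them at adjusted p of 2.87e-05 and 0.000275. With median centring it called 1 gene, lst-1 (log2 fold change -1.75, adjusted p = 0.0282). Over all alternatives run for lst-1 the log2 fold change lay between -1.93 and -1.19, with adjusted p values from 1.07e-11 to 0.797; for sygl-1 it lay between -3.12 and -1.94, with adjusted p values from 4.73e-08 to 0.797. The median log2 fold change of all genes was 0.24, and -0.05 after centring, so the levels of other genes are read against that shift. glp-1 (0.43), gld-1 (0.25), gld-2 (0.50) and lag-1 (0.18) did not pass, and their direction was not stable: lag-1 (-0.11) and gld-1 (-0.043) turned negative with centring, and all 4 did with the length trend removed and without control libraries 1 and 3.

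By camera at the preset correlation, meiotic prophase (adjusted p = 9.16e-08), mitotic cell cycle (0.00137), oogenesis and maternal genes (0.00667) and apoptosis and engulfment (0.0380) were higher at 2 h relative to other genes. X-linked genes (9.16e-08), mitochondrially encoded genes (1.42e-06), known Notch targets (0.00660), intestine markers (0.0291) and ribosomal proteins (0.0311) were lower. None was called with an estimated correlation (adjusted p = 0.999 for each). The medians of known Notch targets (0.26), ribosomal proteins (0.12) and X-linked genes (0.10) were above 0 although their tests were downward. With median centring the ribosomal protein median was -0.18, and with the length trend removed it was 0.058, so its direction depended on the correction. After centring and removal of the length trend, intestine markers were higher in controls 1 and 3 than in controls 2 and 4 (median 0.56, log2). On the deposited scale, which the test used, markers went both ways. There itr-1 was lower in controls 1 and 3 (5.94 and 5.44 against 10.6 and 11.6 CPM). By contrast lbp-6 was higher in them (7.01 and 6.45 against 5.36 and 5.29 CPM). Whether controls 1 and 3 account for the lower intestine markers at 2 h was not tested. The mitochondrial test may depend on controls 1 and 3. atp-6 was 1857 and 1686 CPM in controls 1 and 3 against 1209 and 1185 CPM in controls 2 and 4. Its log2 fold change was 0.056 without controls 1 and 3. nduo-6 was 311 and 276 against 207 and 198 CPM, while ctc-1 was 5899 and 6070 against 5803 and 6361 CPM. Of the meiotic genes, htp-2, a component of meiotic chromosome axes, was 58.4 ± 3.53 CPM (SD, n = 2) against 32.2 ± 5.49 CPM (SD, n = 4), with an adjusted p of 0.404 in limma.

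**Figure D2:**
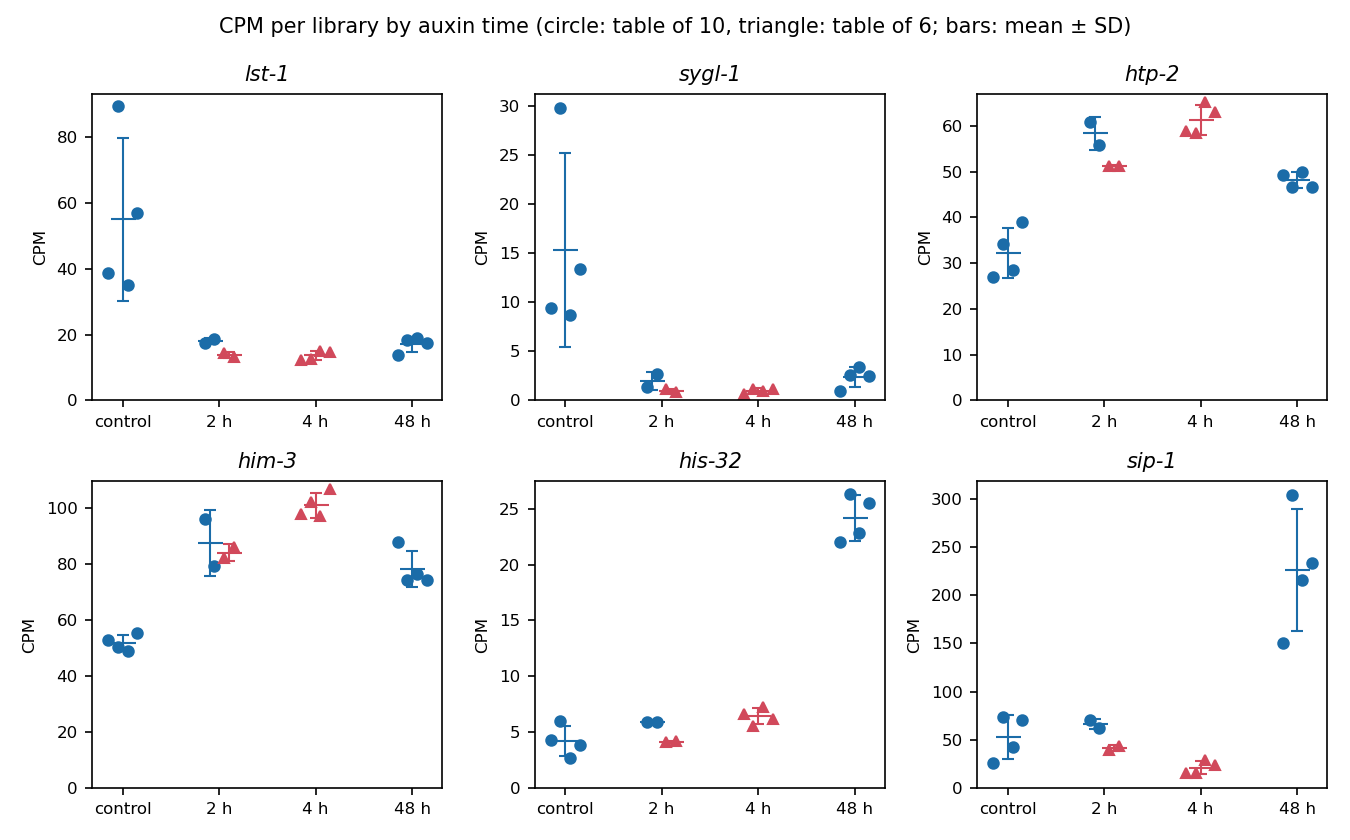
CPM per library (vertical axes) by auxin time (horizontal axes) for lst-1, sygl-1, htp-2, him-3, his-32 and sip-1. Circles are libraries of the 10-library table and triangles of the 6-library table, each with mean and SD per group and table; levels are comparable only within a table. lst-1 reaches 89.5 CPM in controls and lies between 13.9 and 18.9 CPM at 48 h.

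After 48 h, both Notch targets were lower than in controls. lst-1 was 17.1 ± 2.29 CPM (SD, n = 4) against 55.1 ± 24.9 CPM (SD, n = 4), a log2 fold change of -1.54 ± 0.26 (SE, limma adjusted p = 0.00610). sygl-1 was 2.36 ± 1.02 CPM (SD, n = 4) against 15.3 ± 9.89 CPM (SD, n = 4), a log2 fold change of -2.17 ± 0.37 (SE, limma adjusted p = 0.00696). Histone genes were among the largest rises: his-32 rose from 4.21 ± 1.36 to 24.2 ± 2.08 CPM (SD, n = 4 each; log2 fold change 2.30 ± 0.17), his-3 by 1.97 ± 0.12, his-31 by 1.69 ± 0.16 and hil-2 by 1.74 ± 0.25 (log2, SE). Also among the 10 largest rises were sip-1, a small heat shock protein (from 53.1 ± 22.9 to 226 ± 63.4 CPM; log2 fold change 2.14 ± 0.32), cdh-4, a cadherin (2.01 ± 0.32), gei-8, a nuclear receptor corepressor (1.79 ± 0.30), nhr-47 (1.57 ± 0.17), F10G7.5 (1.54 ± 0.13) and C39F7.5 (from 2.87 ± 0.917 to 9.91 ± 2.23 CPM, SD, n = 4 each).

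The 10 largest falls besides sygl-1 and lst-1 were Y69H2.10 (-2.13 ± 0.27), bath-13 (-1.93 ± 0.14), F52D4.1 (-1.76 ± 0.21), C38D9.2 (-1.76 ± 0.23), suca-1 (-1.70 ± 0.34), F40D4.13 (-1.69 ± 0.16), snrp-40.1 (-1.57 ± 0.25) and gas-1 (-1.50 ± 0.39), each a log2 fold change with its SE. All 20 of these genes kept their direction and passed in limma with median centring and with the length trend removed. gas-1 was 3.76 ± 1.60 CPM at 48 h and varied widely in controls (13.8 ± 8.50 CPM, SD, n = 4 each). sip-1, cdh-4, gei-8, nhr-47, Y69H2.10 and gas-1 overlap other annotated genes, and the strand setting of the counting is not given in the sources used here. lag-1, glp-1, gld-1 and gld-2 did not pass at 48 h, with log2 fold changes of 0.24, 0.41, 0.24 and 0.40. Their direction was not stable: lag-1 (-0.043) and gld-1 (-0.041) turned negative with centring, and all 4 did with the length trend removed and without control libraries 1 and 3.

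**Figure D3:**
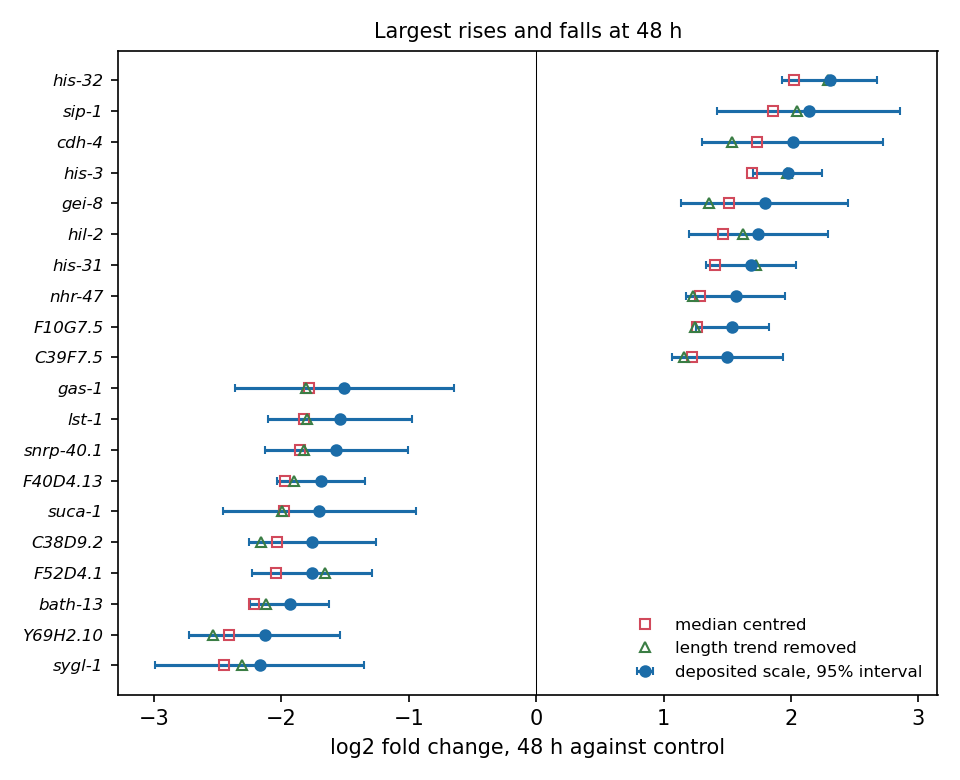
Log2 fold change, 48 h against control (horizontal axis, log2 units), for the 10 largest rises and 10 largest falls (vertical axis). Filled circles with bars are the deposited scale with 95% intervals (n = 4 per group), open squares are median centred and open triangles have the length trend removed; his-32 lies at 2.30, 2.02 and 2.29 and sygl-1 at -2.17, -2.45 and -2.31.

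At 48 h limma called 772 of 7684 genes (564 up, 208 down; 2208 at an unadjusted p under 0.05). The split between rises and falls depended on scaling: after median centring 836 were called (287 up, 549 down), and with the length trend removed 1484 (608 up, 876 down). On the deposited and centred scales 406 genes were called in the same direction (203 up, 203 down). The median log2 fold change of all genes was 0.24, and -0.04 after centring. Without control libraries 1 and 3 the count was 541 (258 up, 283 down), and without these and 48 h library 1 it was 1825 (1180 up, 645 down). edgeR called 888 (392 up, 496 down) and DESeq2 called 1255. Leaving out control 3 gave 376, 48 h library 2 gave 408, 48 h library 3 gave 342 and 48 h library 4 gave 354.

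Among known Notch targets at 48 h, 2 of 8 tested members fell and 0 rose; adjusted over the list alone 3 fell and 1 rose. After centring 4 fell over all genes (lst-1, sygl-1, lip-1 and utx-1) and 1 rose (lst-4). At 48 h utx-1 was 0.146 to 0.225 CPM, near the floor. Control library 3 (0.153 CPM) lay below 48 h library 1 (0.225 CPM), so the fold of utx-1 is not usable. Of 25 tested histone genes, 7 rose and 3 fell (his-5, his-69 and his-67), and after centring 7 rose and 6 fell (these, his-59, his-62 and his-68); near-identical histone copies share sequence, so values per copy are uncertain. In meiotic prophase 6 of 50 members rose and 0 fell, led by prom-1, an F-box protein of meiotic entry (1.14 ± 0.16), and dsb-1, needed for meiotic double-strand breaks (0.63 ± 0.16). After centring 6 also rose and 0 fell, with prom-1, dsb-1 and zim-2 in both sets. The mitotic cell cycle list had 5 of 51 rise, among them cki-2 (0.79 ± 0.18) and cdk-2 (0.72 ± 0.15), and 0 fall; after centring 3 rose (these and cyb-1) and 2 fell (cdc-25.1 and hcp-3). ire-1, the endoplasmic reticulum stress sensor, rose by 1.09 ± 0.21 (1 of 11 members of its list). dpy-27, a dosage compensation gene, rose (1.07 ± 0.17) and tra-3 fell (-0.91 ± 0.19) among 17 sex determination genes. X-linked genes had 21 rise and 26 fall of 319 tested, and after centring 5 rose and 62 fell. The centring shift was estimated on genes of at least 10 CPM. On the log2(CPM + 1) scale it is too large for genes near 1 CPM and moves them toward falls at 48 h. How many of the 62 this concerns was not tested.

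Other lists had few called members at 48 h. Lists can share genes: sygl-1 is counted in both known Notch targets and germline stem cell regulators. Germline stem cell regulators had 1 rise and 2 falls of 23, germline chromatin 2 rises of 28, oogenesis and maternal genes 2 of 42, DNA replication 1 of 37, apoptosis and engulfment 1 of 18 and spermatogenesis 1 of 12. The direction of such small counts depended on scaling. After centring germline chromatin had 0 rises and 1 fall (utx-1, near the floor), and DNA replication had 0 rises and 2 falls (orc-1 and tyms-1). On that scale oogenesis and maternal genes had 3 rises (cpg-1, egg-3 and par-6) and apoptosis and engulfment 2 (ced-4 and lin-45). The Notch pathway (18 tested), germ granule and small RNA (38), ribosomal proteins (80), mitochondrially encoded genes (12) and xenobiotic and oxidative response (7) had 0 called by limma; their members with the smallest p were sel-8, eri-1, rpl-11.2, ctb-1 and sod-1. After centring the Notch pathway had 1 rise (sel-8) and 1 fall (adm-4), and germ granule and small RNA and ribosomal proteins had 1 fall each (alg-5 and rpl-11.2). Immune and infection response had 4 tested members, of which pmk-1 rose, and major sperm proteins had 0 of 31 members tested. Of markers of somatic tissue, muscle markers had 3 rises of 21, somatic gonad markers 2 of 14, and intestine (5 tested), cuticle and epidermis (13) and neurons (13) 1 each, with 1 fall in neurons (unc-31). After centring, 0 muscle markers and 0 intestine markers were called, somatic gonad markers had 1 rise (lin-3), cuticle and epidermis 1 rise (nhr-23) and 1 fall (dpy-9), and neurons 1 rise (unc-33) and 2 falls (unc-31 and egl-21).

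By camera, meiotic prophase was higher at 48 h (adjusted p = 0.0444), and mitochondrially encoded genes (0.000404), X-linked genes (0.00297) and known Notch targets (0.00705) were lower relative to other genes. None was called with an estimated correlation (adjusted p = 0.999 for each). The X-linked median was 0.17 although its test was downward. The high atp-6 levels of control libraries 1 and 3 bear on the mitochondrial test here as well. Within the 48 h group atp-6 was also highest in library 1 (1646 CPM, the rest 1040 to 1197 CPM). ctb-1 by contrast was 1901 to 2179 CPM in 48 h libraries 2 to 4, below every control (2370 to 2729 CPM).

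Between 2 h and 4 h lst-1 and sygl-1 did not pass in limma. lst-1 was 13.7 ± 1.45 CPM (SD, n = 4) at 4 h against 13.8 ± 0.994 CPM (SD, n = 2) at 2 h in the same table, a log2 fold change of -0.01 with a 95% interval of -0.25 to 0.23; sygl-1 was 0.987 ± 0.253 CPM against 0.981 ± 0.219 CPM. Adjusted over the list alone, 1 of 8 known Notch targets rose, utx-1 (0.86 ± 0.20, limma adjusted p = 0.127 over all genes), and 0 fell. In 2 h libraries 3 and 4 utx-1 was 0.11 and 0.177 CPM, at or near their floors of 0.110 and 0.0885 CPM. This fold is therefore not usable. limma called 28 of 7301 genes (13 up, 15 down). The rises were led by tbc-1 (1.25 ± 0.19), rpl-11.2, a ribosomal protein gene (1.08 ± 0.08), pqn-65 (1.06 ± 0.18) and T20F7.1 (0.95 ± 0.16), all on the X chromosome, followed by ife-5, an eIF4E translation factor (0.78 ± 0.08), timm-17B.2, lsy-2, Y73B3A.23, Y39H10A.6 and slc-17.2 (0.77 to 0.43). The falls were B0212.3 (-1.45 ± 0.17), F40D4.13 (-0.99 ± 0.11), F53B6.4 (-0.89 ± 0.12), clec-87, dnj-12, pqn-59, lea-1, klp-15, memi-2 and sams-3 (-0.76 to -0.64), with hrde-1, a nuclear Argonaute, at -0.53 ± 0.09.

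Of X-linked genes 8 of 251 rose and 0 fell between 2 h and 4 h. By camera X-linked genes (adjusted p = 1.41e-08) and mitochondrially encoded genes (6.86e-06) were higher, and oogenesis and maternal genes were lower (0.00561); none was called with an estimated correlation (adjusted p = 0.999 for each). The count rests on 2 libraries at 2 h: without 2 h library 3 it was 4, without 2 h library 4 it was 6, without 4 h library 4 it was 10, and without 4 h library 3 it was 237. Median centring gave 165 and edgeR 233, both including all 28, DESeq2 gave 338, including 26 of them, and the joint fit of both tables gave 0 with limma. At an unadjusted p under 0.05 there were 1133 genes.

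The comparison of 4 h with control joined both tables through the 2 h libraries. Its fold changes add that of 4 h against 2 h to that of 2 h against control, each within its table. Of the meiotic prophase list 3 genes rose: htp-2 by 1.11 ± 0.18, him-3 by 1.00 ± 0.16 and htp-1 by 0.99 ± 0.16 (log2, SE; limma adjusted p = 0.0427 each). The B-type cyclin gene cyb-2.2 rose by 0.87 ± 0.13, and bath-38, C35E7.8, F21F3.4 and F01F1.15 by 0.70 to 1.03. C17H12.36 fell by 0.79 ± 0.13 on the log2 scale. ZK1290.5, which was under the 5 CPM set for naming and is named after its values were seen, fell by 1.397 ± 0.236. htp-1 and htp-2 are close relatives, so their reads may not be fully separated. lst-1 (-1.47 ± 0.38, adjusted p = 0.339) and sygl-1 (-2.30 ± 0.55, adjusted p = 0.279) did not pass in limma over all genes on the deposited scale, and both passed with median centring (-1.69, adjusted p = 0.00547, and -2.52, adjusted p = 0.0227). Over all alternatives run their adjusted p values lay between 1.48e-07 and 0.977 and between 0.00042 and 0.941. Adjusted over the list alone, 2 of 8 known Notch targets fell, these, and 1 rose, utx-1. The link between the tables runs through 2 h libraries 3 and 4, where utx-1 was at or near the floor (0.11 and 0.177 CPM). The rise of utx-1 is therefore not usable.

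limma called 10 of 7240 genes (8 up, 2 down; 418 at an unadjusted p under 0.05), edgeR called 22 and DESeq2 called 94; without control libraries 1 and 3 limma called 8, and without these and 48 h library 1 it called 51. Median centring gave 20 genes, of which 2 were among the 10; htp-2 (0.89, adjusted p = 0.00822) and ZK1290.5 (-1.62, adjusted p = 0.0397) kept their calls, and him-3 (0.78, adjusted p = 0.309) and htp-1 (0.77, adjusted p = 0.180) lost theirs. Leaving out control 2, control 3 or any 2 h or 4 h library gave 0, and leaving out control 1 gave 3, so the calls rest on all of these. In meiotic prophase 3 of 50 rose, and camera was upward for that list (adjusted p = 9.67e-07) and for mitotic cell cycle (0.0450), with neither called with an estimated correlation (adjusted p = 0.999 for each).

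From 2 h to 48 h, within the 10-library table, his-32 rose by 1.86 ± 0.21, his-3 by 1.81 ± 0.15 and his-31 by 1.54 ± 0.19. Of 25 tested histone genes 6 rose and 1 fell; their median was -0.11, and camera did not call the list (adjusted p = 0.505). Other rises were sip-1, gei-8, avr-14, F10G7.5, pho-12, R10E4.1 and nhr-47 (1.71 to 1.16). The falls were Y69H2.10 (-2.59 ± 0.33), C38D9.2 (-2.29 ± 0.28), suca-1 (-2.12 ± 0.42), feh-1 (-2.09 ± 0.32), bath-13 (-2.08 ± 0.17), nhr-145, F40D4.13, cdh-12, snrp-40.1 and Y53G8B.3 (-1.84 to -1.65). The 2 h libraries differed in cdh-12, with 9.06 CPM in library 2 and a higher level in library 1, and cdh-12 was also far higher in 4 h library 3 than in the other 4 h libraries; the column names of 2 h library 1 and 4 h library 3 share a number. lst-1 (-0.08, 95% interval -0.78 to 0.61) and sygl-1 (0.13, 95% interval -0.87 to 1.13) did not pass.

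limma called 219 of 7684 genes, of which 67 (30.6%) were up. Without 2 h library 1 the count was 47 and without 2 h library 2 it was 39; without control libraries 1 and 3 it was 380, without these and 48 h library 1 it was 1561 (884 up, 677 down), and edgeR called 379 and DESeq2 574. Muscle markers were higher by camera (adjusted p = 0.00158), with 0 of 21 called by limma and no call with an estimated correlation (adjusted p = 0.999).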

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

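The counts of genes over other splits of the libraries at 48 h on the deposited scale and over relabellings at 4 h were planned before the data were examined; every other test of an explanation was chosen after its result was seen.

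Of 273 groups of 4 libraries tested for a library far from the other 3, 12 had one, and chance alone would give about 13.65. That figure is a rough guide, since the genes are not independent. The rule also cannot flag a group that splits into pairs, such as controls 1 and 3 against the other controls. At 48 h the gap divided by the range was 0.9067 for lag-1, 0.8847 for gld-2, 0.9043 for cdk-2, 0.8627 for T20F7.1, 0.851 for klp-15, 0.9188 for hrde-1, 0.8328 for him-3 and 0.8753 for feh-1, and in all 8 the far library was 48 h library 1. For pmk-1 it was 0.9637, with 48 h library 3 at 2.14 CPM. At 4 h it was 0.8948 for lev-11 (library 4), 0.9477 for timm-17B.2 (library 1, 97.7 CPM) and 0.9588 for cdh-12 (library 3, 42.7 CPM).

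The limma test of 48 h against 2 h called 25 of the genes named for that comparison. They were named because that same test called them, so the list below is not separate evidence. The log2 difference was 1.864 for his-32, 1.805 for his-3, 1.538 for his-31, 1.708 for sip-1, 1.613 for gei-8, 1.258 for avr-14, 1.254 for F10G7.5, 1.223 for pho-12, 1.176 for R10E4.1, 1.159 for nhr-47 and 0.7151 for F48E3.4. It was -2.59 for Y69H2.10, -2.285 for C38D9.2, -2.117 for suca-1, -2.088 for feh-1, -2.076 for bath-13, -1.844 for nhr-145, -1.772 for F40D4.13, -1.721 for cdh-12, -1.71 for snrp-40.1 and -1.648 for Y53G8B.3. It was -1.283 for unc-31, -1.046 for tra-3, -0.9251 for smz-1 and -0.8209 for his-5.

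Control libraries 1 and 3 and 48 h library 1 differed from the other 7 libraries of their table. A higher share of ribosomal RNA is argued against as the sole cause, since after median centring the longest quintile of genes still differed from the shortest by -0.4823 (log2) in the least extreme of these 3, outside the range of the other 7. A bias by gene length may be part of it: a length trend took up 62.78% of the variance of the deviations between controls 1 and 3 and controls 2 and 4. RNA from other tissues may also be part of it, because with the trend removed 5 of 5 somatic marker lists had medians above 0 by more than their standard errors (intestine 0.56, muscle 0.51, neurons 0.34, cuticle and epidermis 0.85, somatic gonad 0.23), and 5 of 5 lay above the 95th percentile of random lists of like expression; their most abundant genes in controls were itr-1 (8.39 CPM), unc-45 (50.7 CPM), unc-18 (72.7 CPM), nhr-23 (16.16 CPM) and fln-1 (1487 CPM). Those random lists were matched on mean CPM and not on gene length. The centring and length shifts were estimated on genes of at least 10 CPM and may be too large for low markers. In deposited CPM, itr-1 and nhr-23 were lower in controls 1 and 3 than in controls 2 and 4, and lbp-6 was higher. The marker medians thus cannot tell RNA from other tissues from an overcorrection. A length bias and RNA from other tissues both stay open, and no biological explanation was tested.

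That difference between libraries bears on the counts of genes. Each count of splits or relabellings below includes the real grouping. At 48 h against control, 4 of the 35 splits of the 8 libraries gave at least as many genes as the real split (772, highest other 2519), so chance is not excluded. With median centring it was 3 of 35 (836, highest other 1816). With the length trend removed it was 1 of 35 (1484, highest other 402), the lowest share that 35 splits can give. That scale was chosen after seeing the data, so chance is not excluded there either. The larger splits put control libraries 1 and 3 and 48 h library 1 on one side, which points to a structure of the samples. At 4 h against control, 11 of 100 drawn relabellings gave as many genes (10; highest other 4460), so chance is not excluded; the 10 larger ones each set control libraries 1 and 3 together and called at least 2802 genes.

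Some genes were very high in 1 library of each table, at least 3-fold over the median of the other libraries plus 1 CPM. Libraries of the 2 tables whose deposited column names carry the same number shared 10 such genes over 6 pairs. The 54 other pairs shared 2 genes, sre-56 and gas-1. Of 720 matchings of these libraries only the real matching gave as many (highest other 9). frm-2 was at 1033 CPM in 48 h library 3 and 1714 CPM in 4 h library 1, against at most 1.16 CPM in the other libraries, and T24E12.13 was at 297 CPM in 48 h library 4 and 379 CPM in 4 h library 2. Auxin time is argued against, since the 4 pairs of 2 h libraries across the tables shared 0 such genes by this rule. Something tied to the number, such as a shared index or a material handled together, may be the source; which one was not tested, and of the 12 genes gas-1 alone was called in a comparison.

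The 7 histone genes that rose at 48 h had a median log2 fold change of 1.53. In controls his-2 (0.114 CPM) and his-1 (0.221 CPM) were near the floor. Gene length is argued against as the whole cause, since the median was 1.533 with the length trend removed and 7 of 7 were still called. Reads moved between near-identical copies cannot be told apart from a rise: the other histone genes lost 669.1% of the CPM the 7 gained (673 against 101 CPM), but the standard error of that loss, 332 CPM, exceeds the gain. The summed gain also says little about the copies with large folds. his-16, with the smallest fold of the 7 (0.598), alone went from 126.7 to 191.1 CPM. A response to 48 h of auxin stays among the open explanations.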

How the results depend on the processing

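The leaving out of chosen libraries, the removal of the length trend and the leaving out of each 2 h library at 4 h were chosen after seeing the data; the other alternatives were planned. lst-1 and sygl-1 kept a negative log2 fold change against control at 2 h, 4 h and 48 h under every alternative run. These comparisons share the same control libraries. The 4 h fold also contains the 2 h fold, so it is not separate evidence. The library totals of 17760706 to 33888940 reads put the floor of 3 reads at 0.0885 to 0.169 CPM, so genes near it have no usable fold. Where a count or a sign changed, the cause was not tested, except that a stricter filter and fewer libraries test fewer genes or samples.

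For 2 h against control, where 0 genes were called by limma (429 at an unadjusted p under 0.05; edgeR 0), the count was 1 with median centring, 6 with the joint fit of both tables, 29 with DESeq2, 5 with the length trend removed, 0 without control libraries 1 and 3 and 26 without the 3 libraries that stood apart. For 48 h against control (772) it was 383 with the stricter filter, 1534 with the joint fit, 1255 with DESeq2, 1484 with the length trend removed, 541 without control libraries 1 and 3 and 1825 without the 3 libraries, and 342 to 1050 leaving out each library. For 4 h against 2 h (28) it was 9 without a filter, 165 with centring, 10 without the mean-variance trend, 0 with the joint fit (1133 at an unadjusted p under 0.05 in the fit of its own table), 233 with edgeR, 338 with DESeq2 and 273 with the length trend removed, and 4 to 237 leaving out each library. For 4 h against control (10) it was 4 with a pseudocount of 0.1, 0 without a filter, 20 with centring, 5 without the trend, 22 with edgeR, 94 with DESeq2, 75 with the length trend removed, 8 without control libraries 1 and 3 and 51 without the 3 libraries, and 0 to 13 leaving out each library. For 48 h against 2 h (219) it was 42 with the stricter filter, 357 with the joint fit, 379 with edgeR, 574 with DESeq2, 602 with the length trend removed, 380 without control libraries 1 and 3 and 1561 without the 3 libraries, and 39 to 179 leaving out each library. Of the camera tests of a list in a comparison, 19 were called at the preset correlation, 0 with an estimated correlation, 22 with centring and 22 with the length trend removed; a list can count in more than 1 comparison.

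The labels do not say that replicate numbers pair the libraries, and control and 48 h libraries did not pair by number throughout: those of the same number had correlations of deviations of 0.81, 0.62, -0.46 and 0.69. Libraries of different number reached similar values, such as 0.79 for control 3 with 48 h library 1 and 0.68 for control 2 with 48 h library 4. Other pairs of different number were negative, down to -0.87 for control 4 with 48 h library 1. Pairing of the 2 h and 4 h libraries was not checked. With the replicate block the counts were 0 for 2 h against control, 1083 for 48 h against control, 644 for 4 h against 2 h, 0 for 4 h against control (418 at an unadjusted p under 0.05 without the block; edgeR 22) and 233 for 48 h against 2 h, and 19 camera tests of a list in a comparison were called. With the replicate block, the log2 fold changes that changed sign were for 4 h against 2 h lst-1 (0.11), sygl-1 (0.061) and gld-1 (0.067), for 4 h against control lag-1 (0.16) and for 48 h against 2 h lag-1 (-0.014).

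With median centring, the log2 fold changes that changed sign were for 2 h against control lag-1 (-0.11), gld-1 (-0.043), rps-8 (-0.091) and lbp-6 (-0.19), for 48 h against control lag-1 (-0.043), gld-1 (-0.041) and sod-1 (-0.027), for 4 h against 2 h lst-1 (0.068) and sygl-1 (0.081), for 4 h against control gld-1 (-0.064), ctc-1 (-0.018) and pmk-1 (-0.13) and for 48 h against 2 h gld-1 (0.0028). With edgeR on recovered reads, the log2 fold changes that changed sign were for 2 h against control lag-1 (-0.12), gld-1 (-0.051), rps-8 (-0.081) and lbp-6 (-0.21), for 48 h against control lag-1 (-0.056), gld-1 (-0.043) and sod-1 (-0.026), for 4 h against 2 h lst-1 (0.064) and sygl-1 (0.099), for 4 h against control gld-1 (-0.063) and ctc-1 (-0.013) and for 48 h against 2 h gld-1 (0.0076). With DESeq2 on recovered reads, the log2 fold changes that changed sign were for 2 h against control lag-1 (-0.12), gld-1 (-0.048), rps-8 (-0.077) and lbp-6 (-0.21), for 48 h against control lag-1 (-0.055), gld-1 (-0.042) and sod-1 (-0.023), for 4 h against 2 h lst-1 (0.065) and sygl-1 (0.091), for 4 h against control gld-1 (-0.080) and ctc-1 (-0.033) and for 48 h against 2 h gld-1 (0.0065). With the length trend removed, the log2 fold changes that changed sign were for 2 h against control lag-1 (-0.34), glp-1 (-0.074), gld-1 (-0.12), gld-2 (-0.062) and unc-89 (-0.27), for 48 h against control lag-1 (-0.18), glp-1 (-0.0071), gld-1 (-0.11) and gld-2 (-0.039), for 4 h against 2 h lst-1 (0.061) and sygl-1 (0.080), for 4 h against control glp-1 (-0.11), gld-1 (-0.14), gld-2 (-0.15), ctc-1 (-0.021) and pmk-1 (-0.14) and for 48 h against 2 h glp-1 (0.067), gld-1 (0.014) and gld-2 (0.024). With control libraries 1 and 3 left out, the log2 fold changes that changed sign were for 2 h against control lag-1 (-0.37), glp-1 (-0.11), gld-1 (-0.26), gld-2 (-0.031) and atp-6 (0.056), for 48 h against control lag-1 (-0.31), glp-1 (-0.14), gld-1 (-0.27) and gld-2 (-0.13) and for 4 h against control glp-1 (-0.25), gld-1 (-0.36) and gld-2 (-0.24). With 48 h library 1 left out as well, the log2 fold changes that changed sign were for 2 h against control lag-1 (-0.37), glp-1 (-0.11), gld-1 (-0.26), gld-2 (-0.031) and atp-6 (0.056), for 48 h against control lag-1 (-0.18) and gld-1 (-0.13), for 4 h against control glp-1 (-0.25), gld-1 (-0.36) and gld-2 (-0.24) and for 48 h against 2 h lst-1 (0.0099), glp-1 (0.12), gld-1 (0.13) and gld-2 (0.095). Leaving out each library in turn, values that changed sign at least once ranged, for 2 h against control lag-1 (-0.028 to 0.40) and lbp-6 (-0.023 to 0.24), for 4 h against 2 h lst-1 (-0.082 to 0.055) and sygl-1 (-0.11 to 0.11), for 4 h against control gld-1 (-0.042 to 0.33), lag-1 (-0.26 to 0.17) and pmk-1 (-0.15 to 0.33) and for 48 h against 2 h sygl-1 (-0.18 to 0.45), lag-1 (-0.090 to 0.20), glp-1 (-0.15 to 0.12), gld-2 (-0.22 to 0.095), lst-1 (-0.14 to 0.0099) and gld-1 (-0.090 to 0.13).

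Over all alternatives for named genes, 2 h against control gave 507 values with the same sign and on the same side of the threshold, 19 with the same sign that newly passed, 0 with the same sign that no longer passed and 29 that changed sign. The same counts were 1020, 21, 162 and 19 for 48 h against control, 614, 60, 102 and 16 for 4 h against 2 h, 650, 25, 150 and 26 for 4 h against control and 835, 54, 77 and 20 for 48 h against 2 h.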

Other observations

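The tests of X-linked genes among called genes were chosen after the lists had been seen, and so was the look for the gene that stood highest in each library.

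Genes on the X chromosome were more frequent among called genes in 3 sets. Of the 13 genes that rose between 2 h and 4 h, 8 were X-linked protein-coding genes, against 251 of 7301 tested (Fisher's exact test, adjusted p = 1.55e-08 over all directions and comparisons with calls). These were apm-3, lsy-2, pqn-65, rpl-11.2, tbc-1, vps-41, R07E4.5 and T20F7.1. With median centring 14 of 92 rises were X-linked, and without 2 h library 3 or 2 h library 4 only 3 or 4 genes rose in all, so the share depends on scaling and on few libraries. In the 2 h libraries of the other table, tbc-1, rpl-11.2 and pqn-65 were higher than in 2 h library 3 or 2 h library 4, while lsy-2 was similar. Levels are comparable only within a table, so whether this X-linked share marks a change from 2 h to 4 h stays open. Of the 208 genes that fell at 48 h against control, 26 were X-linked, against 319 of 7684 tested (adjusted p = 1.62e-06), among them apm-3, gas-1 and snrp-40.1. Of the genes that fell from 2 h to 48 h, 14 (9.21%) were X-linked (adjusted p = 0.0151), among them apm-3, tbc-1 and suca-1. The 564 rises at 48 h held 21 X-linked genes, 3.72% against 4.15% of genes tested. Genes are not independent, so these p values describe the called lists and not the animals.

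Single libraries held genes far above the rest of their table. In control library 1 iglr-3 was at 18908 CPM, against 3.82 to 5.97 CPM in the other 9 libraries of the table. In control library 2 wht-1 was at 27.01 CPM, against at most 0.0703 CPM in the others. In 2 h library 2 cccp-1 was at 28.3 CPM, against at most 0.771 CPM in the others.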
